A study of Mus musculus with 4 samples.

How the data were processed

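Sub1 CUT&Tag was measured in sorted HSCs and LSCs of mouse bone marrow, with 2 libraries per group and 1 deposited peak list per library. Per the labels, a low-input CUT&Tag kit with an antibody against Sub1 and 17 to 20 PCR cycles was used, and cell numbers are given for HSCs alone. The cell type label reads hematopoietic stem cell for all 4 samples, and groups were taken from the sorting markers and the disease model. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned to mm10 with Bowtie2 2.2.9, called with MACS2 and annotated with ChIPseeker. Handling of duplicate reads is not stated, and reads, coverage tracks and an input or IgG control were not analysed here.

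Each deposited peak carries the authors' fold, a ratio of pileup to background. The authors' lists also give -log10 p and -log10 q for each peak, and a deposited score equal to 10 times -log10 q, rounded down. These values were checked against the caller's formulas: for 3000 peaks sampled per library, fold and -log10 p solved to whole pileups with 1 constant background per library. That background was 3.07 and 7.47 in HSC 1 and HSC 2 and 4.54 and 4.50 in LSC 1 and LSC 2, and it serves as the measure of depth, since read totals were not given. The lowest -log10 q was 5.21, 5.26, 5.36 and 5.41 in the same order.

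Genes came from the RefSeq annotation of GRCm38.p6, the mm10 assembly. The table gives start and end without strand, exons or sequence, so promoters could not be told from 3' ends. A gene counted as occupied when a peak overlapped the window within 1 kb of either annotated end, over 21887 protein-coding genes. The division into exons, introns and untranslated regions and the motif test were not made. Windows moved by 50 kb and 20 random placements served as background. Equal-sized lists held the 34185 peaks of highest -log10 p in each library, the size of the smallest list, and lists of 17092 peaks were also fixed beforehand.

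Group values were compared with a two-sided exact permutation test over all 6 assignments of 4 libraries, whose smallest p is 0.33. Genes and regions found in both libraries of 1 group and neither of the other were counted beside the same counts for pairs of 1 HSC and 1 LSC library. Regions were merged from peaks overlapping by at least 1 bp. For 25 gene lists, chosen with the named-gene rule and the tests before the data were examined, Fisher's exact test (two-sided) compared members with other protein-coding genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Retention asked which genes occupied in both HSC libraries were occupied in both LSC libraries, and gain asked which genes in neither HSC library were. Retention was also set against 10000 random lists matched on decile of HSC rank. In all tests of gene lists the genes are the units, so p-values do not measure the spread between libraries or mice. Genes named are the 10 HSC and 10 LSC genes, and the leading shared genes, whose weaker of 2 (or weakest of 4) peaks ranked highest, list members that differ between groups or lead their list, and a fixed set including Nup214, Sub1 and ferroptosis genes. The fold was used only to describe, rank or filter peaks.

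After the data were seen, the overlap with the peaks of the first library of each group moved by 50 kb, lists of 8546 and 4273 peaks per library, tests of gene lists for presence in 1 group alone at each list size, replication-dependent histone genes, and marker lists for mature neutrophils (31 genes), monocytes and macrophages (20) and early myeloid progenitors (22) were added. Several genes of the marker lists had been looked at before the lists were written. Alternatives were a stricter -log10 q, peaks on autosomes and X alone, a 3 kb window, the summit in place of the peak, overlap of 50% of both peaks, equal-sized lists, ranking by fold, and leaving out each library. Added alternatives were a -log10 q of at least 10, a fold of at least 20, and peaks anywhere in a gene.

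The steps were tested on simulated data and on shortened real lists. Background and pileup were recovered for 100% of 500 simulated peaks at backgrounds of 3.1 and 7.5. The Fisher retention test called 94% of 100 lists with simulated losses and 1.33% of 300 without, for lists of 40 genes, and the rank-matched test called 98% and 0.333%. These lists were drawn at random from genes occupied in both HSC libraries. The rates therefore do not carry over to shorter lists or to lists of genes with weak HSC peaks. With the real HSC lists shortened to the LSC lengths in place of LSC lists, the deposited procedure gave 1008 HSC genes and 0 LSC genes. The equal-sized procedure gave 0 and 0. Each shortened list is part of its own HSC list, so the values of 0 were fixed in advance. They do not show how the procedures treat independent libraries. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.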

Results

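CUT&Tag with an antibody against Sub1, a DNA-binding cofactor of transcription, gave 4 peak lists from sorted mouse bone marrow cells. That the target is Sub1 rests on the labels, since peak names in all 4 lists carry the prefix H4-Cut, which the labels do not explain and which was not interpreted. The groups were hematopoietic stem cells (HSCs, CD48-negative and CD150-positive cells of the Lin-negative, Sca-1-positive, c-Kit-positive fraction) and leukemia stem cells (LSCs, sorted as Lin-negative, Sca-1-negative, c-Kit-positive, CD16/32-positive and CD34-positive cells of mice with MLL-AF9-driven disease), with 2 libraries each. All donors carried 1 floxed and 1 wild-type allele of Nup214, which encodes a nuclear pore protein, and the series title links Nup214 to ferroptosis in LSCs. The comparison asks where Sub1 peaks lie in each cell type, and which genes carry them in 1 group and not in the other. The labels do not say whether libraries of a group came from separate mice, so the spread between libraries cannot be divided into mouse and technique. HSC 1 and HSC 2 had 115881 and 235680 peaks, and LSC 1 and LSC 2 had 41097 and 34185. Read totals were not given, and the background coverage implied by the caller's values was 3.07 and 7.47 reads per position in the HSC libraries and 4.54 and 4.50 in the LSC libraries.

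Sub1 peaks in LSCs were fewer and lay more often at gene ends than in HSCs. Peaks within 1 kb of an annotated start or end of a protein-coding gene, called gene-end peaks here, made up 16.8% and 10.2% of the HSC lists and 31.6% and 36.3% of the LSC lists, against 2.91% of random positions. The means were 13.5% ± 4.64 (SD, n = 2) in HSCs and 33.9% ± 3.28 (SD, n = 2) in LSCs, a difference of 20.5 percentage points. By geometric means, HSC lists held 1.71 times as many gene-end peaks as LSC lists, and 5.79 times as many peaks elsewhere. Away from gene ends, HSC 1 and HSC 2 had 95888 and 210512 peaks, and LSC 1 and LSC 2 had 27862 and 21598. By the same means, HSC lists had 4.41 times as many peaks and covered 2.23 times the length, at 79.0 and 159 Mb against 47.8 and 52.9 Mb. A two-sided exact permutation test gave p = 0.33 for the share, the number and the length, the smallest value that 2 libraries against 2 allow. In lists of 34185 peaks per library the gene-end share differed by 1.0 percentage points, and among peaks with a fold of at least 20, a minimum chosen after the data were seen, HSC 1 and HSC 2 had 8358 and 11798 peaks and LSC 1 and LSC 2 had 12034 and 10572, so the groups overlapped (log2 difference of geometric means 0.18).

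**Figure D1:**
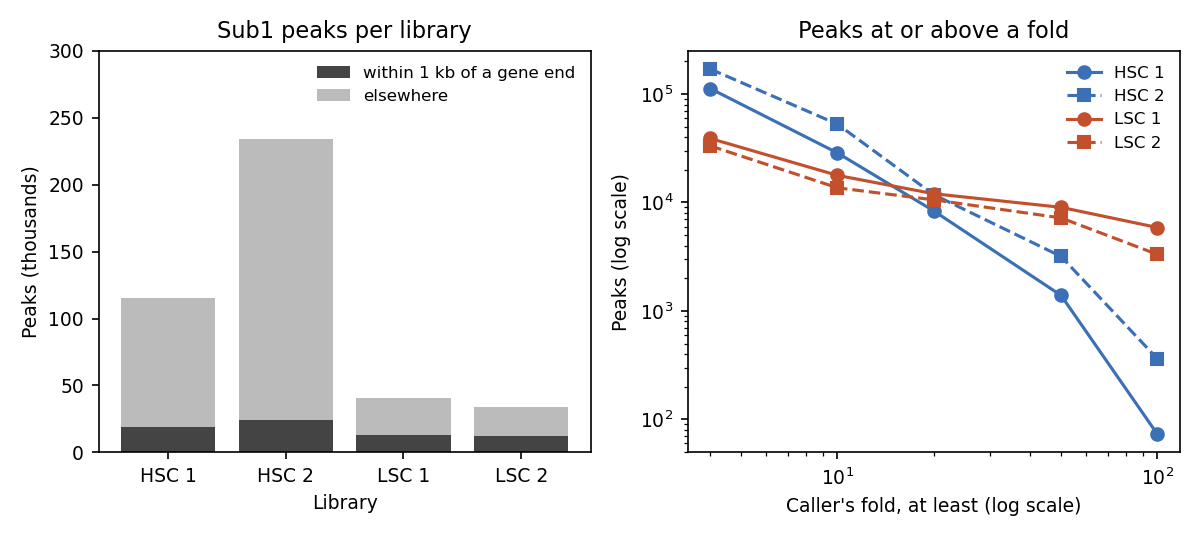
Left, number of peaks on the assembled chromosomes in each library, divided into gene-end peaks (dark) and peaks elsewhere (light). Right, number of peaks at or above a given fold of the authors' peak caller on log axes, with HSC libraries in blue and LSC libraries in red: at a fold of 100 or more HSC 1 and HSC 2 had 73 and 362 peaks, and LSC 1 and LSC 2 had 5875 and 3319.

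The strongest gene-end peaks shared by all 4 libraries lay at Hjurp, which encodes a centromere chaperone, at the pair Maf1 and Sharpin, at the pair Hdlbp and Septin2, at the antigen-processing genes Psmb9 and Tap1, and at the neighbours Gna15, Ncln and S1pr4. The fold of a peak is the authors' caller's value within 1 library and is used here only to describe or order peaks of that library. At Hjurp it was 154 and 253 in the HSC libraries and 517 and 521 in the LSC libraries. The median fold of gene-end peaks was 12.3 and 11.8 in HSC 1 and HSC 2 and 75.6 and 51.6 in LSC 1 and LSC 2. A higher LSC fold at a gene therefore does not show more Sub1 there. Among 21887 protein-coding genes, 10661 had a gene-end peak in all 4 libraries, where 2460 would be expected if libraries were independent. All 75 cytosolic ribosomal protein genes and all 23 genes of the MLL elongation cofactor list had a gene-end peak in every library. Of 41 general transcription and Mediator genes, 40, 41, 41 and 41 had one in HSC 1, HSC 2, LSC 1 and LSC 2, in that order. In the same order the counts were 32, 32, 32 and 31 of 32 nuclear pore genes, 35, 35, 35 and 34 of 35 cell cycle genes, and 51, 50, 49 and 49 of 51 oxidative phosphorylation genes. They were 22, 23, 21 and 21 of 23 glycolysis genes, 28, 29, 29 and 28 of 30 DNA damage response genes, and 22, 25, 23 and 23 of 25 sterol and fatty acid synthesis genes. Each of these lists lay above all other genes in each library, with adjusted p between 5.67e-20 and 0.00294 (Fisher's exact test, two-sided, 100 list and library tests). Genes are not replicates, so this test describes each library.

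Genes of the ferroptosis and iron lists carried Sub1 gene-end peaks in both cell types. Of 36 ferroptosis defence genes, 31 and 36 had a gene-end peak in HSC 1 and HSC 2 and 31 and 30 in LSC 1 and LSC 2, with 29 in all 4. They included Gpx4, the peroxidase that reduces lipid hydroperoxides, Nfe2l2, a regulator of antioxidant genes, Sesn2, Txn1 and Gsr. Gpx4 gene-end peaks had folds of 17.4 and 52.8 in the HSC lists and 124 and 101 in the LSC lists. The HSC 1 value is from a separate peak nearer the high end of the gene. HSC 1 also had a peak of fold 44.7 from 80052011 to 80055140, outside the window. Its summit lay close to those of the other libraries. Pdss2 and Txnrd1 had gene-end peaks in both HSC libraries and neither LSC library, and no gene of this list showed the opposite in the deposited lists. In lists of 34185 peaks per library, Pdss2 was found in HSCs alone, and Fads2 and Mboat1, chosen after their values were seen, in LSCs alone. Slc7a11, which encodes the cystine transporter, had a gene-end peak in HSC 2 alone, with a fold of 3.07, and peaks inside the gene in HSC 1, HSC 2 and LSC 2. Of 31 ferroptosis driver genes, 26, 29, 24 and 24 had a gene-end peak in HSC 1, HSC 2, LSC 1 and LSC 2, and 24 had one in all 4, among them Acsl4, Tfrc, Ncoa4 and Vdac2. Zeb1 and Alox12b had one in both HSC libraries and neither LSC library. Of 30 iron handling genes the counts were 27, 26, 25 and 25, with Fth1, the ferritin heavy chain, and Slc40a1, the iron exporter, in all 4. Of the genes occupied in both HSC libraries, both LSC libraries kept 29 of 31 defence genes, 24 of 26 driver genes and 24 of 26 iron genes, against 87.8% of other genes (adjusted p = 0.657, 0.795 and 0.795, Fisher's exact test, two-sided, 25 lists).

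Genes of the HSC programme and MLL fusion targets carried gene-end peaks less uniformly, and several of their best known members had none. Of 37 HSC programme genes, 19 and 23 had a gene-end peak in the HSC libraries and 19 and 18 in the LSC libraries, and 14 had one in all 4, such as Lyl1, Cxcr4, Gfi1 and Fli1. Lmo2 and Hoxb5 had one in both HSC libraries and neither LSC library, and Cdkn1c the reverse. Mecom and Hlf had no gene-end peak in any library, and had peaks inside the gene in HSC 1, HSC 2 and LSC 1. Of 30 MLL fusion targets, 18, 23, 15 and 15 had a gene-end peak in HSC 1, HSC 2, LSC 1 and LSC 2, with Cdk6, Myc, Myb and Mbnl1 in all 4. Hoxa10, Hoxa11 and Nkx2-3 had one in both HSC libraries and neither LSC library. Hoxa9 had no gene-end peak, but 1 peak inside the gene in each library, on chromosome 6 from 52225541 to 52226006 (mm10) in HSC 1. Meis1 had a gene-end peak in HSC 2 alone. Neither list lay above or below all other genes in any library (adjusted p from 0.492 to 0.857, Fisher's exact test, two-sided).

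In the lists as deposited, 845 genes had a gene-end peak in both HSC libraries and neither LSC library, and 70 genes in both LSC libraries and neither HSC library. By the order fixed before the data were examined, the HSC genes were led by Plin5, which encodes a lipid droplet protein, followed by Dach1, Cd33, Lpcat2, Mmp2, Prom1, Hsd11b1, Mid1, Vsig10l and Lefty1. Their folds ran from 16.5 at Hsd11b1 to 68.7 at Plin5 in HSC 2, and Lpcat2 and Mmp2 shared 1 peak. Plin5 ends at 56117606 on chromosome 17, and its strongest peak lay beyond the gene. That peak ran from 56118253 to 56125037 in HSC 1 and from 56118276 to 56123800 in HSC 2. Other peaks lay within 1 kb of the low end of Plin5 in both HSC libraries. The strongest Lefty1 peak in HSC 2 also began beyond the gene. Whether such peaks belong to neighbouring genes was not tested. The LSC genes were led by Spag11a, Msl3l2, Ttll8, Pcbp3, Slco5a1, Xlr4a, Fgfrl1, Tespa1, Fbp1 and Nr3c2, with folds from 17.5 at Fbp1 to 61.3 at Tespa1 in LSC 1. Pairs that mixed 1 HSC with 1 LSC library had 55, 59, 17 and 247 such genes. The direction turned with list length. In lists of 34185 peaks per library, 108 genes were in both HSC libraries alone and 616 in both LSC libraries alone, against 48 to 77 for mixed pairs. With 17092 peaks the counts were 83 and 784, and with 4273 peaks, a size chosen after the data were seen, they were 331 and 358 against up to 263 for mixed pairs. Without HSC 1 the deposited lists gave 3130 and 166 genes, without HSC 2 they gave 1186 and 312, without LSC 1 they gave 1254 and 93, and without LSC 2 they gave 1071 and 241. The equal-sized lists gave 339 and 1055 genes without HSC 1, 242 and 945 without HSC 2, 181 and 799 without LSC 1, and 221 and 1122 without LSC 2. With 3 ways to part 4 libraries, no test of these counts can pass a threshold of 0.05.

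**Figure D2:**
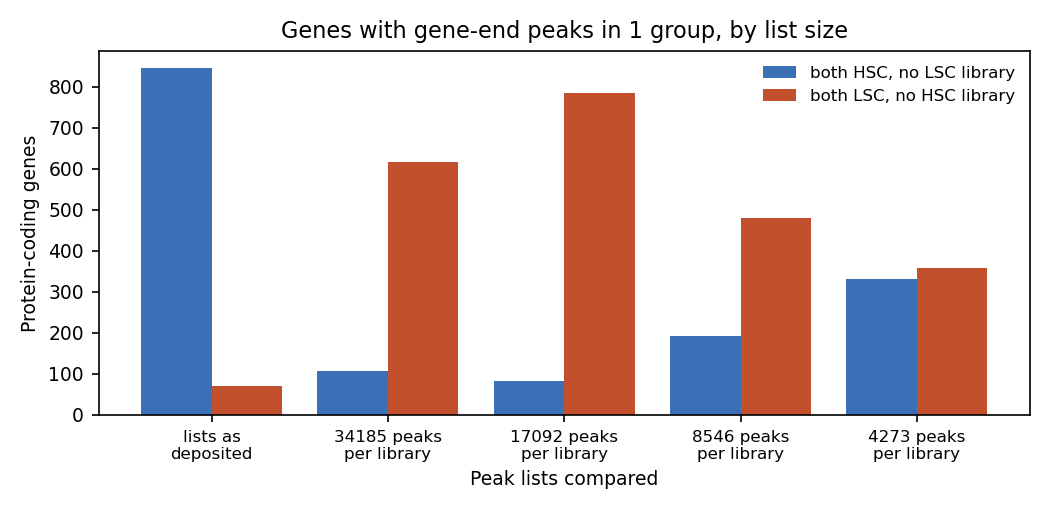
Number of protein-coding genes with a gene-end peak in both libraries of 1 group and neither library of the other, for the lists as deposited and for the strongest peaks of each library at 4 list sizes. HSC genes outnumbered LSC genes 845 to 70 in the deposited lists, while LSC genes outnumbered HSC genes 616 to 108 with 34185 peaks per library.

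Genes of other lineages that carried weak gene-end peaks in HSCs were often without one in LSCs. Of genes occupied in both HSC libraries, both LSC libraries kept 2 of 7 erythroid genes (adjusted p = 0.00378), 3 of 7 B cell genes (0.0203), 3 of 8 T and NK cell genes (0.00544), 1 of 5 endothelial genes (0.00544), 2 of 6 stromal genes (0.0112) and 1 of 7 neuronal genes (5.1e-04), against 87.8% of other genes (Fisher's exact test). Genes seen in HSCs alone included Rhd, Cldn13 and Alas2 among erythroid genes, and Cd3g, Eomes and Gzmb among T and NK cell genes. Both LSC libraries kept 6 of 8 megakaryocyte genes (0.368), 4 of 4 mast cell and eosinophil genes (1.00) and 2 of 4 hepatocyte genes (0.188). All 75 ribosomal genes (0.00141) and 40 of 40 general transcription genes (0.0384) were kept, each above other genes. All are two-sided and adjusted over 25 lists. The 8 lists past the threshold became 15 without HSC 1 and 3 without LSC 2. In a permutation test against 10000 random lists of equal HSC rank no list passed (lowest adjusted p = 0.300, with 2 lists under 0.05 unadjusted). In lists of equal size none passed Fisher's exact test either (lowest adjusted p = 0.0528, 3 unadjusted). With rank or list size taken into account, none of these losses was called.

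**Figure D3:**
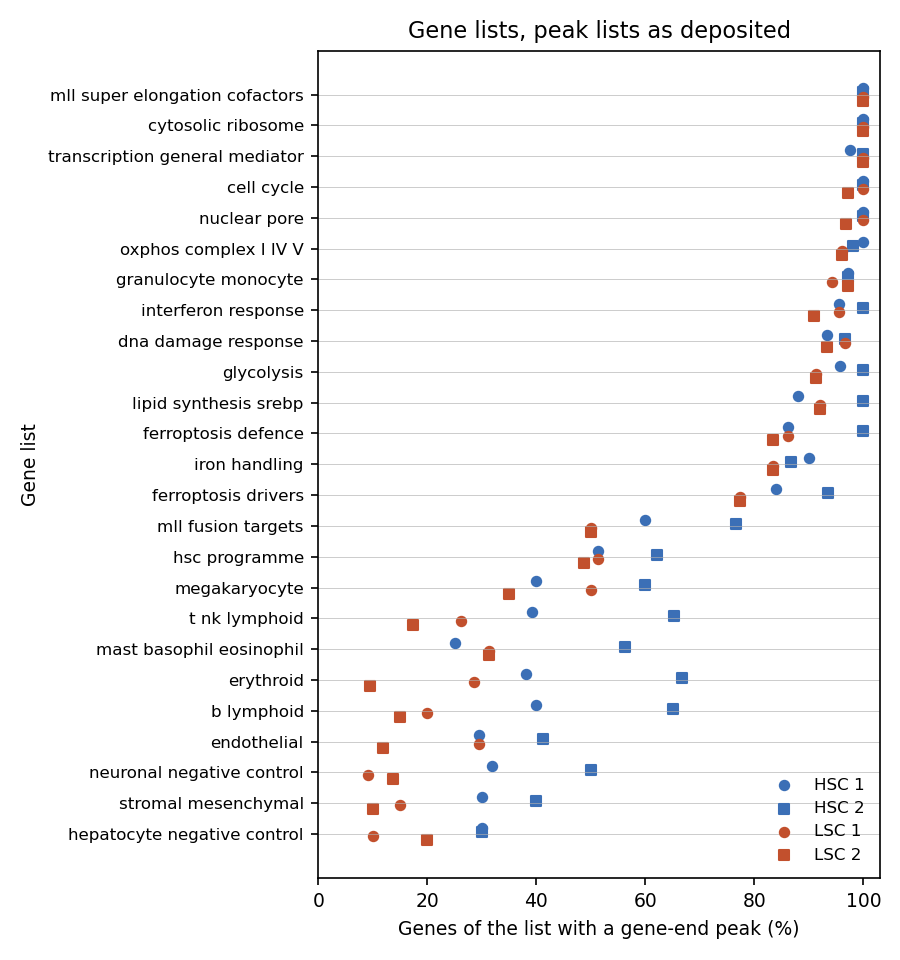
Share of each fixed list's genes with a gene-end peak, in percent, in the deposited lists of HSC 1, HSC 2 (blue), LSC 1 and LSC 2 (red). The cytosolic ribosome list lies at 100% in all libraries, and the neuronal list lies at 31.8% and 50.0% in HSCs against 9.09% and 13.6% in LSCs.

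Among the fixed tests of gain, no list was called as gained in LSCs, but these tests had little room to call one. In the deposited lists the HSC programme had the most genes in neither HSC library, 13. Lists such as the ribosomal genes had 0, so their outcome was fixed in advance. Among genes with a gene-end peak in neither HSC library, 0 of 25 lists differed from other genes in the deposited lists by Fisher's exact test, adjusted or unadjusted. In lists of equal size 0 of 25 passed Fisher's exact test and 3 had an unadjusted p under 0.05, with the HSC programme lowest at 5 of 21 genes (adjusted p = 0.152). A test added after the data were seen took the genes found in both libraries of either group in lists of 34185 peaks and asked which were in LSCs alone. It called the HSC programme (5 of 18 genes compared, Angpt1, Cd34, Cdkn1c, Gata2 and Mllt3, against 5.42% of other genes, adjusted p = 0.0435, Fisher's exact test) and the mast cell and eosinophil list (3 of 5 genes, Gata2, Prg2 and Siglecf, adjusted p = 0.0435, Fisher's exact test). For the mast cell and eosinophil list the adjusted p was 0.0213 with 17092 peaks, 0.0447 with 8546 and 1.00 with 4273 (Fisher's exact test), and rank-matched permutation tests did not call it (0.0735 with 17092 peaks, 0.807 with 8546). For the HSC programme the adjusted p was 0.0682 with 17092 peaks, 0.234 with 8546 and 1.00 with 4273 (Fisher's exact test), and rank-matched permutation tests did not call it (0.257 with 17092 peaks, 0.719 with 8546).

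Among the strongest peaks, genes of mature neutrophils and of the interferon response were found more often in HSC than in LSC libraries. This comparison used the 8546 strongest peaks of each library, a size chosen after the data were seen, and a neutrophil marker list written after several of its genes had been looked at. Genes are not replicates, so p-values in this paragraph describe these lists and not the spread between libraries or mice. Of 31 neutrophil genes, 21 and 17 had a gene-end peak among them in HSC 1 and HSC 2, and 5 and 9 in LSC 1 and LSC 2. Clec4e, Cxcr2, Il1r2, Itgam, Ltf, Mmp25, Ngp, Padi4 and S100a9 were in both HSC libraries and neither LSC library (50.0% of 18 list genes compared, against 2.14% of other genes, adjusted p = 2.7e-09, Fisher's exact test, two-sided, 58 tests). Some of the 9 lay at the limit of the LSC lists: the Padi4 peak ranked 8544 by fold in LSC 2 and fell outside through ties, and the Clec4e peak ranked 8604 in LSC 1. Of 22 interferon response genes, a list fixed beforehand, 19 and 19 were found in HSCs and 13 and 14 in LSCs, and Ddx58, Ifit1, Isg15, Oas2 and Rsad2 in HSCs alone (adjusted p = 9.2e-04, Fisher's exact test). For interferon genes the adjusted p was 0.0307 with 4273 peaks, 0.11 with 17092 and 1.00 with 34185 (Fisher's exact test). The interferon genes in HSCs alone changed with list size. They were Ifih1, Irf7, Oas1a, Oas2 and Usp18 with 4273 peaks, and Ifit1 and Isg15 with 17092. Of 35 granulocyte and monocyte genes, 33 and 33 were found in HSCs and 24 and 30 in LSCs (adjusted p = 0.304, Fisher's exact test), with Itgam, Ngp and S100a9, which the neutrophil list also holds, in HSCs alone and Mpo, Elane, Prtn3, Ctsg and Cebpa in all 4 libraries. Cd34, Kit and Gata2, genes of early progenitors, were found in both LSC libraries and neither HSC library, but their list did not pass (3 of 15 genes compared, adjusted p = 0.342, Fisher's exact test). Tal1, of the HSC programme, was in HSCs alone, but Cd34, Kit and Gata2 also belong to that list. The 3 HSC programme genes in LSCs alone, of 11 compared, did not pass (adjusted p = 0.234, Fisher's exact test). Ribosomal genes numbered 73, 73, 73 and 74 of 75 in HSC 1, HSC 2, LSC 1 and LSC 2. In percentage points of the list, neutrophil genes differed less at other sizes. They numbered 30, 26, 21 and 26 among 34185 peaks (adjusted p = 0.0435) and 9, 8, 1 and 3 among 4273 peaks (0.0171, Fisher's exact test). Of the 7 list genes compared with 4273 peaks, 57.1% were in HSCs alone, namely Cd177, Il1r2, S100a8 and Wfdc21. With 34185 peaks they were Ccl6, Il1b and Retnlg, so the neutrophil genes in HSCs alone also changed with list size. In the deposited lists, the interferon response had 21, 22, 21 and 20 genes, and the granulocyte and monocyte list 34, 34, 33 and 34, so these lists differed in the order of peaks more than in their presence. Neutrophil genes also differed in presence, with 31, 31, 23 and 26 of 31 in the deposited lists. Those lists are of unequal size, and among 34185 peaks HSC 2 and LSC 2 both had 26.

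**Figure D4:**
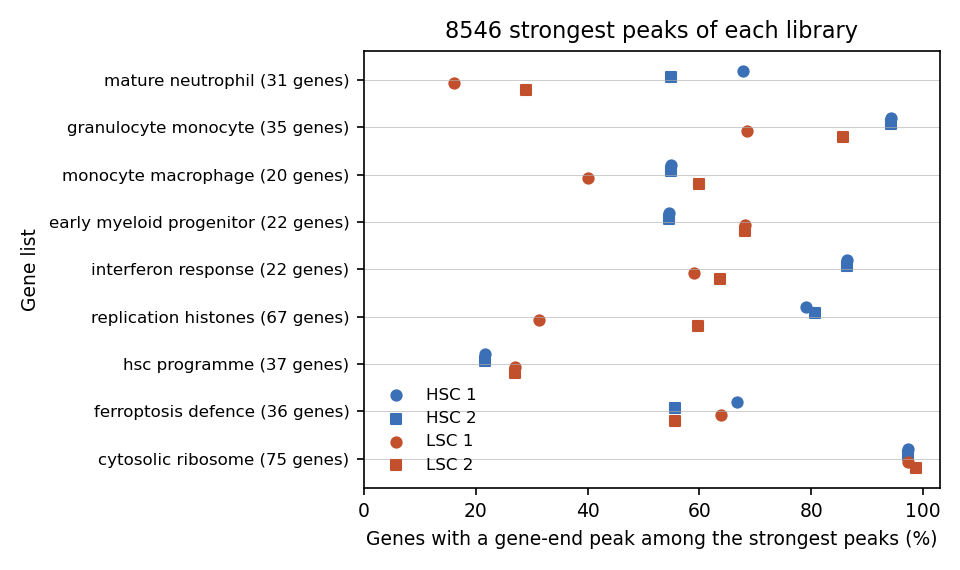
Share of genes of 9 lists with a gene-end peak among the 8546 strongest peaks of each library, in percent, with HSC libraries in blue and LSC libraries in red. Neutrophil genes lie at 67.7% and 54.8% in HSCs and at 16.1% and 29.0% in LSCs, and cytosolic ribosomal genes lie near the top in all 4 libraries.

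Among genes of the sorting markers, Ly6a and Slamf1 had peaks in the HSC lists alone. The others had gene-end peaks in both groups, including Cd48, although HSCs were sorted as CD48-negative. Ly6a, which encodes Sca-1, had gene-end peaks in HSC 1 and HSC 2, with folds of 9.33 and 12.2, and no peak in or near the gene in either LSC library. Slamf1, which encodes CD150, had a gene-end peak in HSC 2 alone. Counted anywhere in or near the gene, it had peaks in both HSC libraries and in neither LSC library. In HSC 1 this was 1 peak with a fold of 4.67, where the lowest fold of the list was 3.93. The highest fold in HSC 2 was 10.2. Cd48, Fcgr3 and Fcgr2b, the latter genes encoding CD16 and CD32, and Kit had gene-end peaks in all 4 libraries. Cd34 had one in HSC 2, LSC 1 and LSC 2. These genes, apart from Cd34, were chosen after their values were seen, and presence was compared between lists of unequal size.

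Nup214 and Sub1 themselves carried gene-end peaks in all 4 libraries. The Nup214 peak lay at the low end of the gene on chromosome 2, from 31974055 to 31975397 (mm10) in HSC 1, with folds of 33.2 and 60.3 in the HSC lists and 207 and 173 in the LSC lists. The Sub1 peak lay at the high end of the gene on chromosome 15, from 11994481 to 11996822 in HSC 1, with folds of 24.8, 22.5, 93.4 and 38.7 in HSC 1, HSC 2, LSC 1 and LSC 2. The median gene-end fold was higher in both LSC lists than in both HSC lists, so the folds do not compare Sub1 between groups. Both groups carried the floxed Nup214 allele, so these peaks do not compare Nup214 genotypes.

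Counted as regions of the genome, 15515 regions had a peak in all 4 libraries, and 61.2% of them touched a gene end. In the deposited lists 22346 regions were found in both HSC libraries and neither LSC library, of which 9.31% touched a gene end, and 995 regions in both LSC libraries and neither HSC library. Away from gene ends, 32116 regions were in both HSC libraries, and 22789 still were with the peaks of HSC 1 moved by 50 kb. For the LSC libraries the counts were 8587, and 2166 with LSC 1 moved. All peaks of the moved library were shifted, those at gene ends included. With 34185 peaks per library, 1766 regions were in HSCs alone and 3873 in LSCs alone, and 5888 and 8142 regions away from gene ends were in both libraries of a group. In those equal-sized lists 57.3% of peaks overlapped between the HSC libraries and 63.3% between the LSC libraries. Pairs of 1 HSC and 1 LSC library overlapped for 51.4% to 58.5% of peaks, so libraries of a group were 5.80 percentage points closer on average, and random placement gave about 4.29% at most. The overlap of the HSC libraries lay inside the range of the mixed pairs. For the deposited lists, regions in HSCs alone numbered 197210 without HSC 1 and 77637 without HSC 2. Regions in LSCs alone numbered 1836 without HSC 1, 2682 without HSC 2, 4151 without LSC 1 and 9125 without LSC 2.

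Transfer RNA genes had peaks more often than windows moved by 50 kb, at 62.7%, 71.3%, 58.3% and 57.8% of 408 genes in HSC 1, HSC 2, LSC 1 and LSC 2, against 34.3%, 47.8%, 18.9% and 19.6%. Small nuclear RNA genes, at 16.8%, 28.8%, 9.56% and 9.66% of 1004, lay near the moved windows at 14.5%, 29.7%, 8.27% and 6.87%. Protein-coding genes had a gene-end peak in 57.8%, 68.4%, 54.6% and 52.1% of cases, against 33.8%, 53.0%, 20.0% and 19.2% for moved windows.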

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

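The tests in this part were chosen after the results were seen, except the comparison of gene-end and other regions at equal fold. Peaks on patch or unplaced sequences, which no comparison of the report by gene uses, numbered 680 and 1262 in HSC 1 and HSC 2 and 353 and 299 in LSC 1 and LSC 2. They drew attention as signal outside the assembled chromosomes, and no control library sets their background.

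LSC lists held far fewer peaks away from gene ends than HSC lists. Fewer reads behind the LSC lists could account for this against HSC 2, since background coverage per base of the smallest peak width was 0.479 times that of HSC 2 in LSC 2 and 0.588 times in LSC 1. The tables argue against it for HSC 1, where the ratios were 0.993 and 1.22 while peaks were 3.39 and 2.82 times fewer. Whether 1 common loss of sensitivity acted is not decided. At HSC folds of 10 to 15, both LSC lists kept 73.0% of gene-end regions and 39.1% of others, a gap of 33.9 percentage points. The bound of 10 points written beforehand was not exceeded in every band (9.18 below a fold of 5, 1.23 from 25 to 50 and 7.59 above). In those bands shares near 0% or 100% leave little room. Away from gene ends, 32116 regions were in both HSC libraries, and 22789 with HSC 1 moved by 50 kb. All peaks of the moved library were shifted, those at gene ends included, so the moved counts are no matched level of chance. Overlap by chance could also lower the share kept there, to an extent that was not measured. Peaks without replicate support in the HSC lists stay open, since regions away from gene ends found in both libraries of a group were 3.74 times as many in HSCs, but 1.45 times as many beyond those found with 1 library moved by 50 kb and 0.723 times as many in equal-sized lists. Cell number, antibody or tagmentation efficiency, duplicates, batch and a biological difference between HSCs and LSCs are confounded with the groups and stay open.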

How the results depend on the processing

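Alternatives with a -log10 q of at least 10, a fold of at least 20, peaks anywhere in a gene, lists of 8546 peaks, all neutrophil values and the covered length without 1 library were chosen after seeing the data. Of 131 alternatives, 82 left the result within its bounds, 40 moved it and 9 reversed it. Gain of gene lists stayed at 0 under all 10 of its alternatives. Many lists had few or no genes in neither HSC library, so a gain in them could hardly be called. A -log10 q of at least 5 removed no peak, and ranking by fold gives the order of -log10 p when 1 background serves a library, so both test nothing.

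List size reversed the gene and region counts. Equal-sized lists gave 108 HSC and 616 LSC genes, 1766 and 3873 regions, a gene-end share difference of 1.0 points and 0 lists in retention by Fisher's exact test (3 unadjusted). A fold of at least 20 gave a log2 peak number difference of 0.18, a share difference of 3.31, 69 and 889 genes, and 167 and 1405 regions. Both settings remove the weaker peaks by construction. For the other changes below, the cause was not tested.

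Lists of 17092 peaks gave 0 lists in retention (2 unadjusted) and a concordance difference of 9.17. Rank matching gave 0 lists (2 unadjusted), and matching in lists of 8546 peaks 2 lists. The 3 kb window gave 34 LSC genes. The summit gave 129 LSC genes, 165 HSC genes in equal-sized lists and 5 lists. Overlap of 50% gave 11895 and 3894 regions. A -log10 q of at least 10 gave 3 lists. Peaks anywhere in a gene gave 1687 and 21 genes and 17 lists. Lists of 8546 peaks gave 193 HSC genes. The neutrophil difference of 38.7 points was 14.5 with 34185 peaks, 14.5 with 17092 and 21.0 with 4273.

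Without 1 library at a time, HSC genes ranged from 1071 to 3130 and LSC genes from 93 to 312, and in equal-sized lists from 181 to 339 and from 799 to 1122. Retention ranged from 3 to 15 lists, HSC regions from 25754 to 197210, LSC regions from 1836 to 9125, the log2 peak number from -2.65 to -1.63, the log2 covered length from -1.66 to -0.65, the share difference from 17.2 to 23.7 and the neutrophil difference from 32.3 to 45.2. The highest HSC counts came without HSC 1, and retention fell to 3 lists without LSC 2.

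A replicate block left the values of -2.14, -1.16 and 20.5 with p = 0.5 (exact permutation), the smallest 2 pairs allow, and nothing states that replicate numbers pair libraries. Motif alternatives were not run, and genome sequence was not used here.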

Other observations

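The tests in this part were all chosen after the results were seen. Chromatin of mature neutrophils in the HSC libraries is a candidate source of the strong neutrophil gene peaks, as a hypothesis without an independent test: the smallest difference in share between an HSC and an LSC library, 25.8 percentage points among the 8546 strongest peaks, restates the pattern, and sort purity was not analysed here. In the ranking of each library's own peaks, the median neutrophil gene lay in the top 5.98% and 3.04% in HSC 1 and HSC 2, and the median of the 19 and 23 HSC programme genes with a peak in the top 14.5% and 11.5%. Early myeloid progenitor genes (3.93% and 1.76%), monocyte and macrophage genes (5.42% and 1.01%) and granulocyte and monocyte genes (2.61% and 0.648%) ranked higher still, so the source stays open. Among abundant neutrophil genes, folds in HSC 1 and HSC 2 were 44.0 and 64.1 at S100a8, 30.9 and 34.4 at S100a9, 52.1 and 71.5 at Lcn2 and 21.6 and 33.9 at Camp, and Ly6g had gene-end peaks there and none in LSCs. In LSC 1 and LSC 2 the folds were 30.3 and 51.6 at S100a8, 12.4 and 21.4 at S100a9, 34.1 and 93.8 at Lcn2 and 11 and 39.4 at Camp, and Trem1 and Trem3, which share 1 peak in each LSC library, were in LSCs alone among 17092 peaks. The Lin-negative, Sca-1-positive, c-Kit-positive gate of the HSC sort would remove such cells, and 6 of the 31 genes are also in the granulocyte and monocyte list.

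Displacement by stronger peaks at other gene ends stays open. Among the 8546 strongest peaks, both LSC libraries kept 4 of 17 neutrophil genes of the HSC lists. Lists of equal HSC rank kept 15.7 (13 to 17 in the central 95%, permutation p = 0.0002, the smallest these can give, adjusted p = 0.00387). With 17092 peaks 16 of 21 were kept, against 20.5 in matched lists (adjusted p = 0.00387, permutation). With 4273 peaks 1 of 7 was kept, against 5.72 (0.0174, permutation). Several genes of this list had been looked at before it was written. The test therefore partly restates the pattern and cannot decide against displacement. A drop of all lineage-restricted genes stays open: 121 genes of 6 other lineage lists differed by -0.826 percentage points (HSC minus LSC, so slightly higher in LSCs), but with 4.96% and 5.79% in HSCs they had little room to drop. Differentiation state, cell handling and batch are confounded with the groups and stay open, as does lower Sub1 binding at these genes in LSCs.

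Whether neutrophils account for moves of other lists was not tested. In the same permutation test the LSC libraries kept 13 of 19 interferon response genes (18.0 in matched lists, adjusted p = 0.00696), 24 of 33 granulocyte and monocyte genes (31.3, 0.00387) and 7 of 11 monocyte and macrophage genes (10.4, 0.0329). These calls depended on list size: with 17092 peaks the LSC libraries kept 33 of 33 granulocyte and monocyte genes and 11 of 11 monocyte and macrophage genes (1.00 each, permutation), with interferon still called (0.0116), and with 4273 peaks the 3 lists gave 0.0696, 1.00 and 0.554 for granulocyte and monocyte, monocyte and macrophage, and interferon genes. For early myeloid progenitor genes no such loss was called (11 of 12 kept, 11.4 in matched lists, 1.00). Of 67 replication-dependent histone genes, 53 and 54 had a gene-end peak among the 8546 strongest peaks in HSC 1 and HSC 2 and 21 and 40 in LSC 1 and LSC 2, and the LSC libraries kept 20 of 50 (47.0 in matched lists, 0.00387), 60 of 61 with 17092 peaks (1.00, permutation) and 0 of 27 with 4273 peaks (19.4 in matched lists, 0.0116). Clustered histone genes share peaks, so these genes are not independent. Of 20 monocyte and macrophage genes 11, 11, 8 and 12 had such a peak, and of 22 early myeloid progenitor genes 12, 12, 15 and 15. Gata2 and Siglecf, of the mast cell and eosinophil list, had one in both LSC libraries alone (adjusted p = 0.0447, Fisher's exact test), which the rank-matched permutation test did not call (0.807, and 0.0735 with 17092 peaks).

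The highest peak of every library lay on chromosome 2 from 98666228 to 98667342 (mm10), with folds of 92615, 83449, 9543 and 41434 in HSC 1, HSC 2, LSC 1 and LSC 2. Its pileup in HSC 1 was 377066, against a background of 3.07. Regions of extreme signal were not filtered out here, and no control library was analysed. Whether this peak reflects Sub1 or an artifact of mapping was not tested. LSC 1 had a peak of 8326 bp beside Ighm on chromosome 12, from 113422880 to 113431205, which covered Ighj1 to Ighj4 and Ighd4-1. By fold, the strongest peak in this stretch ranked 2 in LSC 1 and 8 in LSC 2, and 24 and 23 in HSC 1 and HSC 2. The HSC peaks were shorter and ended at 113426196 and 113427638, before Ighj4, which begins at 113428514.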
